A study of Danio rerio with 8 samples.

How the data were processed

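Whole ovaries of adult female zebrafish of the AB strain were profiled on Affymetrix 3' expression arrays after 15 days on feed carrying 0 (solvent only), 10, 40 or 100 ppb (ng per g of feed) of TCDD, a tetrachlorinated dibenzo-p-dioxin that activates the aryl hydrocarbon receptor. Per the labels' protocols and the series' design text, the RNA of 5 ovaries per dose, 3 µg from each fish, was combined into 1 pool, and each of the 4 pools was hybridised on 2 arrays. The 8 samples are therefore 4 pools measured as technical replicates. P-values from the fit of arrays measure the spread between arrays of a pool. Those of the dose trend use the spread of 4 pool means around a line. Those of exposed against control, gene lists included, use the spread of the 3 exposed pools around their mean, dose differences included. The single control pool is assumed there to vary like them. None of these measures variation between fish.

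The deposited table holds 1 intensity per probe set and array, on a linear scale. Per the submitters' processing notes these intensities are MAS5 signals; the MAS5 version, its scaling target and any filter are not given in the sources used here. The instrument files deposited beside the table hold settings of the fluidics station and scanner, a unit other than expression per the file headers, and were used only to group the arrays by day. Replicate 1 of the 0, 40 and 100 ppb pools shared a day (day 2), replicate 1 of the 10 ppb pool stood alone on day 1, and replicate 2 of every pool was run on day 3. Of 15617 probe sets, 115 controls were left out. Among the other 15502, the platform annotation gave 1 gene symbol to 10795 and several to 135, and 4572 were unnamed here; no gene was named from a probe set with several symbols. Symbols were checked through 10711 gene identifiers in a current gene table, which updated 1. No genome was used, so no coordinates are given.

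The 2% trimmed mean intensity ranged from 96.1 to 212 between arrays, so the deposited intensities share no common scale. The design written before the data were examined kept the deposited scaling and listed quantile normalization as an alternative. Once the array levels had been seen, and before any test was run, quantile normalization became the reported scaling, and the counts in the deposited scaling are given beside it. Values were log2(intensity + 16), quantile normalized between arrays. Differences are on this scale, which understates changes of dim probe sets. Probe sets above the 40th percentile of mean log2 value (5.11) were tested, 9301 in all, of which 7566 had 1 symbol, for 6335 genes. The 95th percentile of 17 tag control probe sets, which match no zebrafish transcript, was 5.92 to 20.5 in intensity, and 63.6% to 79.5% of probe sets per array lay above it. A probe set under that percentile on both arrays of a pool has only a bound there. It was computed as the mean of the brighter pool minus the mean, over the arrays of the dimmer pool, of the higher of its own value and the lowest value above the percentile, all as normalized log2 values. The number of arrays and pools limits the precision.

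Pools were compared with limma (lmFit on the 4 group means over all 8 arrays, eBayes with a variance trend, Benjamini-Hochberg adjustment within each comparison). A probe set was counted when its adjusted p was under 0.05 and its log2 difference at least 1 in size. Residual degrees of freedom were 4, and 10.5 with the prior. The SE given is that of the difference in this fit. With the pools as samples (1 mean per pool, 2 residual degrees of freedom), limma tested the 3 exposed pools against the control pool and the slope on the rank of the dose, at an adjusted p under 0.05 without a minimum difference. Gene lists fixed before the data were examined were tested with limma's camera on the fit of exposed against control pools, with the correlation between genes preset to 0.01 and 1 probe set per gene (the brightest). There were 15 pathway lists, including aryl hydrocarbon receptor targets, steroid synthesis, vitellogenins, lipid and retinoid metabolism, stress, cell cycle, ribosomal proteins, oxidative phosphorylation and extracellular matrix. Another 8 lists held markers of cell types, among them neighbouring organs such as liver and pancreas. For each list and dose the median difference was set against 10000 random lists of equal size and like expression.

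The genes named are, by a rule fixed beforehand, the 10 largest passing differences each way per dose against control (5 for dose against dose) with both exposed arrays on 1 side of both control arrays and 1 symbol, placeholder symbols passed over. The rule adds those passing at all 3 doses, the 10 with the smallest p each way in the pool fits, and up to 4 passing members of each list with its best known member. It did not ask for every gene it selects to be printed. Against the control pool it selects 1 gene not named below, a2m3d (lower at 10 ppb). For 40 against 10, 100 against 10 and 100 against 40 ppb 3, 2 and 5 of 10 are named for that comparison, and of the 20 with the smallest p in the trend and in exposed against control 10 and 4 are named. Per gene the probe set with the largest difference was taken, or the brightest for list members outside the top ranks. tiparp, fabp10a and rbp4 are members of the fixed lists that did not pass and were chosen after their values were seen. Of 91 passing gene comparisons named, 19 had other tested probe sets of the same gene, 20 in total; all 20 had the same sign and 12 also passed.

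The scripts' tests were checked on simulated data made from these arrays. For 100 ppb against 0 ppb the array fit recovered 99% of probe sets changed by 1.5 and 100% of those changed by 2.5, with 3 false calls among the other probe sets of 9301. The exposed-against-control pool fit recovered 73% and 89% with 9 false calls, and the trend recovered 88% at 0.75 per rank and 92% at 1.25 with 5 false calls. camera with the preset correlation called a list of 64 genes shifted by -0.3 and none of 21 other lists; with an estimated correlation it called none. Overlaps of comparisons against the shared control were set against 50 simulations of unchanged groups with the observed array spread.

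Alternatives covered the scaling, the pseudocount, the filter, the variance trend, blocks by replicate number and by day, the arrays in the fit, the minimum difference, the dose scale, the pools and the list test. Fits without the 10 ppb arrays, and without probe sets discordant between them, were added after the data were seen, as were the other filters on the liver list, the bounds for dim probe sets and the estimated correlation under other settings. Software was R 4.3.3 with limma 3.58.1, and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. A feed of higher dose that the labels' protocols mention was not analysed here. vtg1 and pck1, the best known members of 2 lists, were not among the tested probe sets.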

Results

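The series measured which transcripts of the zebrafish ovary respond to dietary TCDD, with a control pool and pools fed 10, 40 and 100 ppb, 2 arrays each. The median intensity per array lay between 28.1 and 62.25. After normalization the arrays of a pool correlated across 15502 probe sets (which are not independent replicates) at r = 0.992 for 0 ppb, 0.981 for 10 ppb, 0.992 for 40 ppb and 0.991 for 100 ppb. Between its arrays the 10 ppb pool had 190 of 9301 tested probe sets that differed at least 2-fold, against 20, 9 and 13 in the 0, 40 and 100 ppb pools. The ratio of 3' to 5' signal of the gapdh control probe sets was 1.38 and 1.34 on the 0 ppb arrays, 1.22 and 1.52 at 10 ppb, 1.23 and 1.16 at 40 ppb, and 0.949 and 1.06 at 100 ppb. The 10 brightest probe sets held 2.17% and 2.87% of the signal at 0 ppb, 3.02% and 3.53% at 10 ppb, 2.84% and 3.30% at 40 ppb, and 2.95% and 3.58% at 100 ppb. Differences below are log2 differences between pools ± SE (2 arrays per pool), with limma's adjusted p. The SE pools the array spread over the 4 pools, so a probe set has 1 SE at every dose. Where the 10 ppb arrays lay far apart, SE and adjusted p understate the spread at 10 ppb. An example is serpina1l, at 10.84 and 8.885 on those arrays. Where the lower pool read below the tag controls on both arrays, the difference is a bound, given as at least N-fold; this held for 6 of 103, 1 of 32 and 10 of 116 probe sets that passed at 10, 40 and 100 ppb, and for 16 of 91, 16 of 148 and 4 of 40 between exposed pools.

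The comparison of 10 ppb with the control pool asked what the lowest dose changed. hpxb, a hemopexin gene for heme transport, rose by 4.65 ± 0.36 (25.1-fold, adjusted p = 0.000109) and the protease inhibitor gene serpina1l by 4.37 ± 0.45. Ceruloplasmin (cp) rose by 3.93 ± 0.51, complement c3a.1 by 3.84 ± 0.53, and complement c9 by 3.61 ± 0.46. Plasminogen (plg) rose by 3.51 ± 0.41, transferrin (tfa) by 3.46 ± 0.26 and fibrinogen beta (fgb) by 3.43 ± 0.46. The methyltransferase gene bhmt rose by 4.35 ± 0.48 and the mitochondrial uncoupling protein gene ucp1 by 3.44 ± 0.40. The vitellogenin genes, which encode yolk precursors, fell, with differences of -2.96 ± 0.44 for vtg2, -2.75 ± 0.34 for vtg4 and -2.09 ± 0.23 for vtg3. cyp1a, the cytochrome P450 gene that the dioxin receptor activates, rose by 2.49 ± 0.32 (5.6-fold, adjusted p = 0.00349).

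Of 21 tested genes on the liver list, 12 rose, 1 (vtg2) fell and 8 did not pass; adjusted over the list alone, 16 rose and 1 fell. The list's median was 2.73, above all 10000 random lists. The filter's mean includes the 10 ppb arrays, so that a rise there can carry a gene past it. Without a filter 11 of 27 genes rose and 1 fell (33 listed, median 1.95), and with the mean of the 6 other arrays as the filter, chosen after the data were seen, 8 of 13 rose and 1 fell (median 3.2). Other lists hold 3 of the 21 (vtg2, apobb.1 and rbp4), and tfa and vtg2 lay above the median gene in both control arrays. The 10 ppb arrays differed in these transcripts: tfa stood at 11.65 on replicate 1 and 10.63 on replicate 2 against 7.62 and 7.74 in the control arrays, vtg2 at 7.04 and 8.83 against 10.75 and 11.04, and cyp1a at 8.60 and 7.27 against 5.37 and 5.53. The liver marker fabp10a differed by 0.32 ± 0.30 and rbp4 by -0.39 ± 0.39, and neither passed; in the deposited scaling fabp10a turned to -0.01. Between the arrays of the shared day fabp10a differed by -0.38 and rbp4 by -1.35. rbp4 passed as lower with day as a block (-1.33) and without 10 ppb replicate 1 (-1.23). Of 5 genes on the estrogen receptor and vitellogenin list, 3 fell and 2 did not pass, with 3 also adjusted over the list alone.

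Single members rose at 10 ppb in the lists for lipid metabolism (apobb.1, an apolipoprotein gene, 3.30 ± 0.42, 1 of 12), growth factors (igfbp1a, 2.19 ± 0.39, 1 of 13) and leukocytes (lysozyme, lyz, 1.07 ± 0.15, 1 of 12), each also adjusted over its list alone. A second probe set of igfbp1a differed by 1.69 and did not pass. Of 6 aryl hydrocarbon receptor genes, cyp1a alone passed, at this dose and at both others, over all genes and adjusted over the list alone. Decreases outside the lists had differences of -2.56 ± 0.20 for ctsl.1, a cathepsin L protease gene, and -2.2 ± 0.17 for the glycosyltransferase gene gbgt1l4. The receptor subunit gene chrnb3b was at least 2.35-fold lower (adjusted p = 0.00586), a bound. Other differences were -1.61 ± 0.25 for the ependymin-like gene epdl2, -1.32 ± 0.22 for neurod6b, -1.29 ± 0.17 for the galectin gene lgals2a and -1.13 ± 0.16 for the keratin gene krt18b. Of these genes hpxb and plg read below the tag controls on 1 of 2 control arrays, and ctsl.1 on 1 of 2 arrays at 10 ppb.

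Of 9301 probe sets 103 passed at 10 ppb, 60 higher and 43 lower (58.3% higher), and 133 with day as a block. The 10 brightest probe sets held 3.02% and 3.53% of the signal at 10 ppb against 2.17% and 2.87% in the control arrays. That block took pmaip1, krt18b and lyz under the minimum difference of 1, with 0.94, -0.91 and 0.94 at 10 ppb. All 103 had the same sign between the arrays of the shared day, which selection from these same arrays nearly fixes. There 89 of the 103 differed by at least 1, and cyp1a differed by 1.74. In the deposited scaling, which shifted the median of all probe sets by -0.34, 64 passed, 45 higher and 19 lower (70.3% higher), 60 of them shared, and cyp1a missed the threshold there and without either control array, with adjusted p up to 0.0712. More were lower than higher without control replicate 1 (28, of which 12 higher and 16 lower), without control replicate 2 (19, 8 and 11), without 10 ppb replicate 1 (123, 54 and 69), with only the compared pools (42, 19 and 23), with the filter at the 60th percentile (37, 17 and 20) and with no minimum difference (226, 108 and 118). The count was 192 (116 higher, 76 lower) without 10 ppb replicate 2, and 47 (11 higher, 36 lower) without the liver list and probe sets discordant between the 10 ppb arrays, a restriction chosen after the data were seen. Of the 25 calls named, bhmt, ctsl.1, gbgt1l4, hpxb, serpina1l, tfa and vtg3 passed in each fit without 1 array that tested them (a gene can drop under the filter there); 14 of the others ended without control replicate 1, 18 without control replicate 2 and 3 without 10 ppb replicate 1.

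**Figure D1:**
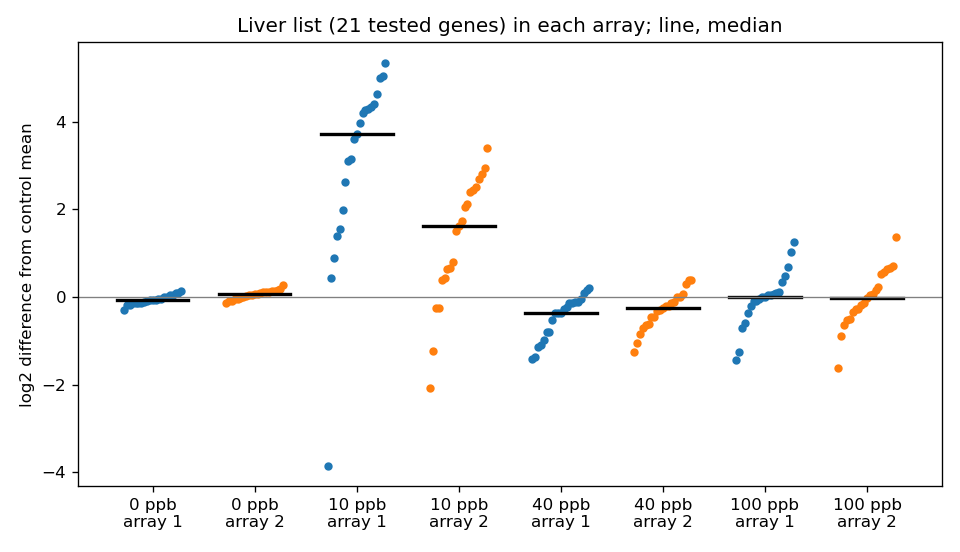
Each point is 1 of 21 tested liver list genes on 1 array (x axis, pool and array), as the log2 difference from the mean of the control arrays (y axis), and lines are medians. The pool-level median was 2.73 at 10 ppb, -0.29 at 40 ppb and 0.04 at 100 ppb, and the 10 ppb arrays differ from each other, with tfa at 11.65 and 10.63.

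At 40 ppb cyp1a rose by 3.13 ± 0.32 (8.78-fold, adjusted p = 0.00211). The other 3 increases were crp, an acute-phase pentraxin gene, by 1.32 ± 0.17, the pro-apoptotic gene pmaip1, by 1.32 ± 0.17, and btr22, by 1.05 ± 0.16; a second probe set of pmaip1 differed by 0.39 and did not pass. anxa1a and anxa2a, which encode calcium-dependent phospholipid-binding annexins, fell, with differences of -1.90 ± 0.125 and -1.67 ± 0.14 (adjusted p = 0.000166 and 0.000634). The epithelial keratin genes krt4, krt94, krt18b and krt8 fell, with differences of -1.51 ± 0.185, -1.34 ± 0.14, -1.21 ± 0.16 and -1.11 ± 0.15.

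The potassium channel gene kcnn1b was at least 3.10-fold lower at 40 ppb (adjusted p = 0.0422), a bound. Further decreases had differences of -2.11 ± 0.23 for tcnbb, which encodes a cobalamin carrier, -1.95 ± 0.18 for ctsl.1, -1.91 ± 0.185 for the actin-binding thymosin gene tmsb1 and -1.44 ± 0.24 for tm4sf21a; tcnbb and ctsl.1 read below the tag controls on 1 of 2 arrays at 40 ppb. Of 12 leukocyte genes, 2 fell and 10 did not pass: cpa5, a carboxypeptidase gene of mast cells, at -1.56 ± 0.24 and the macrophage scavenger receptor gene marco at -1.04 ± 0.19. On the list for extracellular matrix and remodelling 2 of 25 fell, krt4 and krt8, which encode intermediate filaments inside cells. One member each fell in the lists for red blood cells (ca2, carbonic anhydrase, -1.06 ± 0.17, 1 of 2), adipose and endothelium (cebpa, -1.06 ± 0.20, 1 of 4) and glycolysis (gapdhs, -1.02 ± 0.13, 1 of 21). The counts for these 5 lists were equal adjusted over the list alone. None of 21 liver genes and of 10 retinoid genes passed in limma's test over all genes, 1 in each was lower adjusted over the list alone, and the liver median was -0.29.

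Of 9301 probe sets 32 passed at 40 ppb, 4 higher and 28 lower (12.5% higher), and 41 with day as a block. All 32 had the same sign within both shared days, which selection from these same arrays nearly fixes. There 24 differed by at least 1 on day 2 and 27 on day 3. cyp1a differed by 3.38 on day 2 and 2.89 on day 3. Both 40 ppb arrays had a lower gapdh 3' to 5' ratio (1.23 and 1.16) than both control arrays (1.38 and 1.34). In the deposited scaling, which shifted the median by 0.14, 4 passed, 1 higher and 3 lower (25% higher): cyp1a, tcnbb, ctsl.1 and kcnn1b, all shared. The count was 10 without control replicate 1, 8 without control replicate 2, 7 without 40 ppb replicate 1 and 12 without 40 ppb replicate 2, and cyp1a missed the threshold without control replicate 1 or 40 ppb replicate 1 (adjusted p up to 0.0611). Of the 20 calls named, anxa1a, anxa2a, ctsl.1 and tmsb1 passed in each fit without 1 array; 13 of the others ended without control replicate 1, 14 without control replicate 2, 16 without 40 ppb replicate 1, 12 without 40 ppb replicate 2 and 7 each without 100 ppb replicate 1 or 2.

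At 100 ppb cyp1a rose by 4.04 ± 0.32 (16.4-fold, adjusted p = 7.96e-05). anxa1a and anxa2a fell, with differences of -2.64 ± 0.125 and -2.12 ± 0.14. So did krt18b at -2.16 ± 0.16, krt4 at -2.04 ± 0.185, krt94 at -1.97 ± 0.14, krt8 at -1.57 ± 0.15 and krt18a.1 at -1.5 ± 0.15. Other decreases had differences of -2.53 ± 0.24 for cpa5, -2.18 ± 0.17 for gbgt1l4, -2.07 ± 0.14 for f13a1b, a coagulation factor XIII subunit gene, -1.93 ± 0.22 for neurod6b (below the tag controls on 1 of 2 arrays) and -1.73 ± 0.17 for lgals2a. As bounds, ctsl.1 was at least 4.06-fold lower (adjusted p = 9.3e-05) and tcnbb at least 3.67-fold lower (adjusted p = 0.000294).

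Increases at 100 ppb beside cyp1a included crp by 1.65 ± 0.17, ptgdsb.1, a prostaglandin D synthase gene, by 1.40 ± 0.17, lratd1 by 1.39 ± 0.25 and vstm2lb by 1.37 ± 0.15. tmem263 rose by 1.74 ± 0.26, the epithelial adhesion gene epcam by 1.59 ± 0.24, snu13a by 1.44 ± 0.27, pmaip1 by 1.40 ± 0.17 and the sialyltransferase gene st8sia7.1 by 1.40 ± 0.18, but a second probe set of each of these 5 genes did not pass, with differences of 0.21, 0.23, 0.47, 0.31 and 0.11. tiparp, a further target of the dioxin receptor, differed by 0.96 ± 0.16 (adjusted p = 0.00901), under the minimum difference of 1.

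On the list for extracellular matrix and remodelling, 5 of 25 genes fell at 100 ppb and 20 did not pass, with 6 lower adjusted over the list alone. They were krt4, krt8 and krt18a.1, the fibronectin gene fn1b (-1.03 ± 0.20) and the collagen-degrading protease gene ctsk (-1.40 ± 0.23). In the leukocyte list 2 of 12 fell, cpa5 and marco (at least 2.33-fold lower, adjusted p = 0.00374). Both tested red blood cell genes fell, hbaa1 at -1.24 ± 0.17 and ca2 at -1.31 ± 0.17, and 2 of 6 muscle genes, the smooth muscle genes acta2 (-1.15 ± 0.145) and tagln (-1.0 ± 0.14). One gene each fell in lipid metabolism (apoeb, -2.0 ± 0.23, 1 of 12), retinoid metabolism (rbp2a, -1.46 ± 0.21, 1 of 10), oxidative stress (txnb, -1.32 ± 0.23, 1 of 24), glycolysis (gapdhs, -1.64 ± 0.13, 1 of 21) and adipose and endothelium (cebpa, -1.37 ± 0.20, 1 of 4). Apart from the matrix list, these counts were equal adjusted over each list alone. Of 5 estrogen receptor and vitellogenin genes none passed in limma's test over all genes at 40 or 100 ppb, and 2 were lower at 100 ppb adjusted over the list alone. None of 21 liver genes passed by either adjustment, and their median was 0.04.

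Of 9301 probe sets 116 passed at 100 ppb, 28 higher and 88 lower (24.1% higher), and 130 with day as a block. All 116 had the same sign within both shared days, which selection from these same arrays nearly fixes. There 103 differed by at least 1 on day 2 and 97 on day 3. cyp1a differed by 4.11 on day 2 and 3.96 on day 3. The gapdh 3' to 5' ratio was 0.949 and 1.06 at 100 ppb against 1.38 and 1.34 in the control arrays, and the 10 brightest probe sets held 2.95% and 3.58% of the signal against 2.17% and 2.87%. In the deposited scaling 13 passed, 1 higher and 12 lower (7.69% higher), all 13 shared; cyp1a, anxa1a, krt18b, cpa5, tcnbb, ctsl.1 and neurod6b were among them, and krt4, krt8, krt94 and anxa2a were not. The count was 74 without control replicate 1 and 69 without control replicate 2. Of the 36 calls named, 24 passed in each fit without 1 array that tested them, cyp1a, anxa1a, anxa2a, krt18b, krt4, krt94, krt8 and krt18a.1 among them; 10 of the others ended without control replicate 1, 8 without control replicate 2, 6 without 100 ppb replicate 1 and 9 without 100 ppb replicate 2.

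**Figure D2:**
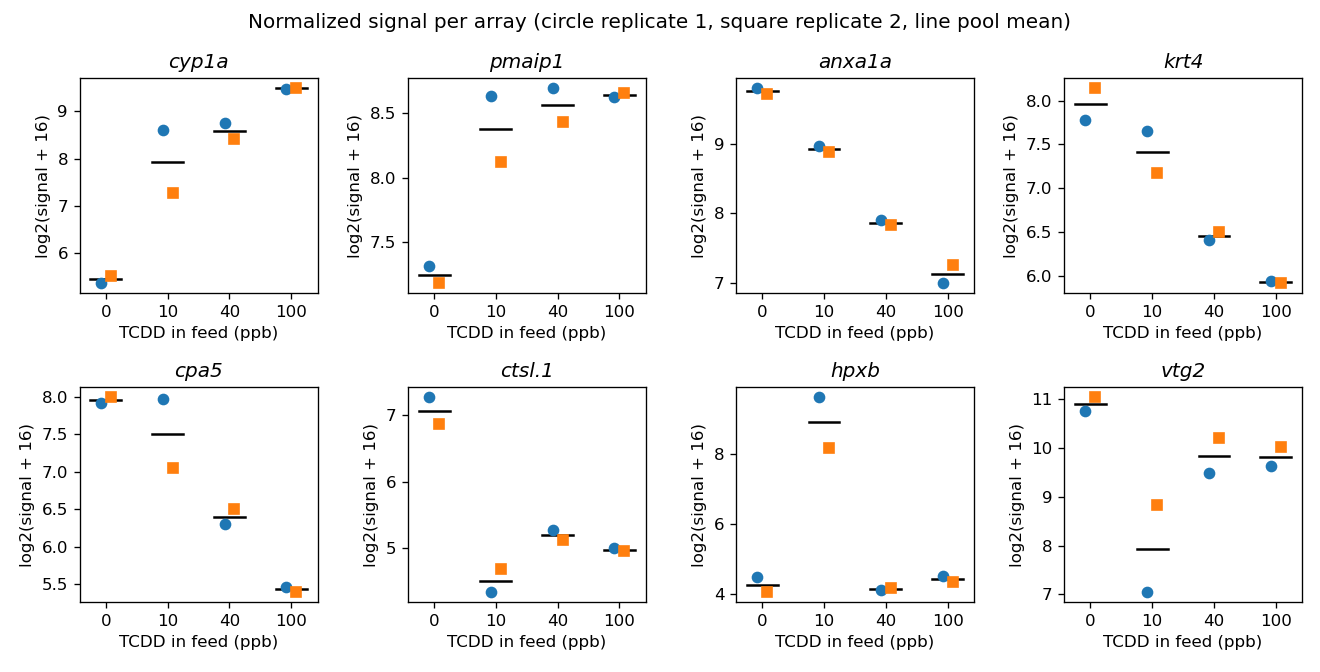
Normalized log2(intensity + 16) of 8 genes (y axes) against TCDD in feed in ppb (x axes), 1 point per array (circle replicate 1, square replicate 2), with lines at pool means. cyp1a rose at every dose, anxa1a, krt4 and cpa5 were lower at 40 and 100 ppb, and hpxb stood out at 10 ppb, where its arrays read 9.63 and 8.19.

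The genes of the 3 doses overlapped. At all 3, cyp1a and pmaip1 rose (a second probe set of pmaip1 differed by 0.30, 0.39 and 0.31 and did not pass), and 7 probe sets fell, including those of ctsl.1 and krt18b; independent lists of these sizes would share 7.77e-05 and 0.00122. At 40 and 100 ppb 24 probe sets fell in common (0.265 for independent lists) and 3 rose (0.012). The medians of the 24 were -1.34 at 40 ppb and -1.63 at 100 ppb, and 21 carried 1 symbol. At 10 and 40 ppb 8 fell (0.129) and 2 rose (0.0258), and at 10 and 100 ppb 17 fell (0.407) and 5 rose (0.181). These comparisons share 1 control pool, so their lists are not independent, and the overlap at all 3 doses was not simulated. Simulated unchanged groups shared 0.1, 0.04 and 0.06 calls for these 3 pairs in the same order. Correlations across probe sets were 0.650, 0.404 and 0.429 against 0.502, 0.499 and 0.501 simulated, and covariances 0.0579, 0.0385 and 0.0573 against 0.0151, 0.0150 and 0.0150. The correlations of 0.404 and 0.429 lay below their simulated values. The simulated arrays varied only as arrays of 1 pool do, with equal spread in every pool. Neither a control pool unlike the others nor the wider spread of the 10 ppb arrays was simulated. The controls are 2 arrays of 1 pool, too few to keep 2 arrays in each part of a split. Part or all of the overlap may therefore come from the shared control pool. For pairs of differences that share no pool, r was 0.197 (40 minus 0 with 100 minus 10), 0.185 (10 minus 0 with 100 minus 40) and 0.0047 (100 minus 0 with 40 minus 10).

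Between exposed pools, hpxb was at least 16.9-fold lower at 40 than at 10 ppb (adjusted p = 0.000181) and at least 17.5-fold lower at 100 than at 10 ppb (adjusted p = 0.000141), and tfa was lower at 40 ppb (-4.66 ± 0.26). gbgt1l4 was higher at 40 than at 10 ppb by 1.82 ± 0.17, and vtg2 was higher at 100 than at 10 ppb by 1.89 ± 0.44 (adjusted p = 0.0442), a call that ended whichever array was left out other than 10 ppb replicate 2. Between 40 and 10 ppb 91 probe sets passed, 28 higher and 63 lower (30.8% higher), and between 100 and 10 ppb 148, 48 higher and 100 lower (32.4% higher). All had the same sign within the shared day, which selection from these same arrays nearly fixes. There 84 of 91 and 138 of 148 differed by at least 1. With day as a block 132 and 236 passed. In the deposited scaling, which shifted the medians by 0.48 and 0.27, 61 passed in each, 11 higher and 50 lower (18.0% higher), of which 51 and 57 were shared; median scaling shifted the first by 0.10. Between 40 and 10 ppb the count was 35 without 40 ppb replicate 1, 42 without 40 ppb replicate 2 and 160 without 10 ppb replicate 2; between 100 and 10 ppb it was 71 without 100 ppb replicate 1 and 68 without 100 ppb replicate 2.

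From 40 to 100 ppb, neurod6b, f13a1b and the apolipoprotein gene apoeb fell, with differences of -1.90 ± 0.22, -1.86 ± 0.14 and -1.65 ± 0.23 (adjusted p = 0.00285, 0.000195 and 0.00982), while ptgdsb.1 rose by 1.57 ± 0.17 and id3, a transcriptional inhibitor gene, by 1.45 ± 0.17. In all 40 probe sets passed, 15 higher and 25 lower (37.5% higher), and 59 with day as a block. The 40 had the same sign within both shared days, which selection from these same arrays nearly fixes. There 32 differed by at least 1 on day 2 and 38 on day 3. The deposited scaling, with a shift of -0.19, gave 4, 0 higher and 4 lower, all shared, and of the genes named here neurod6b alone passed. The count was 20 without 40 ppb replicate 1, 10 without 40 ppb replicate 2, 10 without 100 ppb replicate 1, 15 without 100 ppb replicate 2, and 62 without 10 ppb replicate 2. f13a1b passed whichever array was left out; of the 5 named, 1 ended without 40 ppb replicate 1, 4 without 40 ppb replicate 2, 4 without 100 ppb replicate 1 and 2 without 100 ppb replicate 2.

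**Figure D3:**
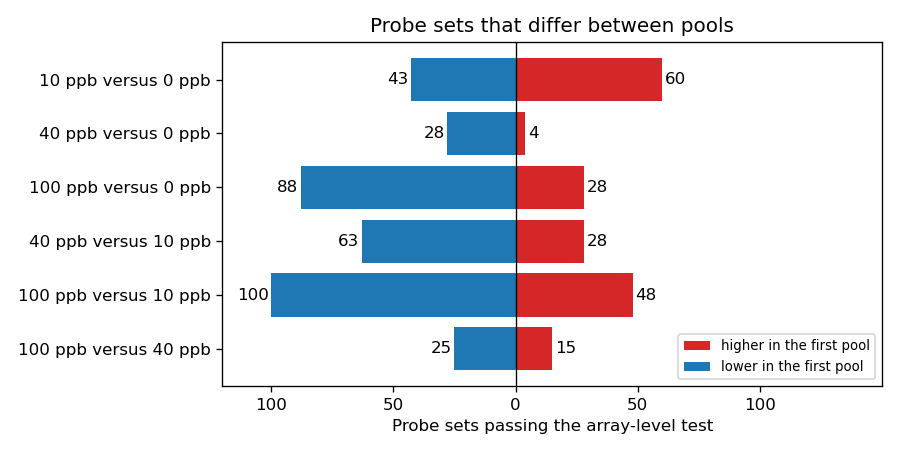
Bars give the probe sets that passed the array-level test (x axis) in each comparison of 2 pools (y axis), higher in the first pool to the right and lower to the left. Lower probe sets outnumber higher ones except for 10 ppb against 0 ppb, with 60 higher and 43 lower, where lower ones led in some other settings (12 higher and 16 lower without control replicate 1).

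With each pool as 1 sample, anxa1a and krt94 fell with dose across the 4 pools, with slopes of -0.90 ± 0.05 (SE) and -0.67 ± 0.05 per rank of dose (adjusted p = 0.0127 and 0.0461). cyp1a, whose pool differences were 2.49, 3.13 and 4.04, had a slope of 1.28 per rank (adjusted p = 0.196). These 2 were the trend's calls, and 1133 probe sets had an unadjusted p under 0.05. Pool means followed the order of dose, rising or falling, in 14.5% of probe sets, 738 rising and 607 falling. Each order with its reverse takes 8.33% by chance, and the order 0, 40, 10, 100 ppb took 13.3% and 10, 0, 40, 100 ppb 10.4%. For the 3 exposed pools against the control pool limma called 0 probe sets (smallest adjusted p = 0.648), with 701 at an unadjusted p under 0.05. With the 10 ppb pool taken as the odd one in place of the control it called 66, and 0 with the 40 or 100 ppb pool, where 64 and 845 had an unadjusted p under 0.05. In the deposited scaling the trend called 19 (2 higher, 17 lower), anxa1a and krt94 among them, and exposed against control 24 (6 higher, 18 lower). The trend called 123 without the 10 ppb pool, 4 without the 40 ppb pool, and 0 without the 100 ppb pool. It called 6 without control replicate 1, 7 without 10 ppb replicate 1, and 1 without control replicate 2, 10 ppb replicate 2, 40 ppb replicate 1, 40 ppb replicate 2 or 100 ppb replicate 1. anxa1a passed whichever array was left out. Both calls ended without a variance trend, with dose in ppb and without the 100 ppb pool, and krt94 ended in 10 of 20 settings against 3 of 20 for anxa1a.

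Among the fixed lists, leukocyte genes were lower in exposed pools (mean -0.45, 12 genes, camera adjusted p = 0.00158), as were extracellular matrix and remodelling genes (-0.36, 25 genes, adjusted p = 0.0034), while oocyte genes were higher (0.12, 27 genes, adjusted p = 0.0374). Each had adjusted p = 0.800 with an estimated correlation. In simulated data that test missed a list of 64 genes shifted by -0.3, so its lack of calls cannot decide whether a list shifted. The simulated genes were independent, so the preset correlation was not checked on correlated genes. The control arm of every list test is 1 pool, so whatever sets that pool apart enters each list's shift. On day 3, which all pools shared, the 10 brightest probe sets held 2.87% of the signal in the control array and 3.53%, 3.30% and 3.58% at 10, 40 and 100 ppb, with a gapdh 3' to 5' ratio of 1.34 against 1.52, 1.16 and 1.06. Within day 2 their means were -0.58, -0.33 and 0.16, within day 3 -0.45, -0.37 and 0.11, and with day as a block -0.46, -0.31 and 0.12. At the preset correlation these 3 also passed with median scaling (adjusted p = 0.000189, 0.00174 and 3.67e-06) and in the deposited scaling (3.11e-08, 1.33e-07 and 8.53e-06). The oocyte list missed the threshold without control replicate 1 (adjusted p = 0.117), without 40 ppb replicate 1 (0.0691), without the 100 ppb pool (0.0672), with the filter at the 60th percentile (0.0544) and on ranks (0.0671), and the matrix list with that filter (0.130). No oocyte gene passed at any dose over all genes, and 1 was higher at 100 ppb adjusted over the list alone. The leukocyte list was below 0 in 10 of 12 genes at 10 ppb, 11 of 12 at 40 ppb and 11 of 12 at 100 ppb.

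Cytosolic ribosomal protein genes were lower by a mean of -0.15 (64 genes, adjusted p = 4.04e-11, and adjusted p = 0.800 with an estimated correlation), but their direction was up with median scaling (adjusted p = 0.501) and in the deposited scaling (0.832). Oxidative phosphorylation genes were lower by -0.12 (47 genes, adjusted p = 0.000129, and adjusted p = 0.745 with an estimated correlation) and glycolysis genes by -0.18 (21 genes, adjusted p = 0.0103, and adjusted p = 0.800 with an estimated correlation). Neither passed with median scaling (0.0686 and 0.106) or in the deposited scaling (0.244 and 0.0939). With day as a block their means were -0.14 and -0.22. Cell cycle genes differed by 0.08 (27 genes, adjusted p = 0.0507, and adjusted p = 0.800 with an estimated correlation). At the preset correlation they passed with median scaling (0.000189), in the deposited scaling (0.01), with pseudocount 64 (0.0492) and without a filter (0.0324). They also passed without 10 ppb replicate 1 (0.0262), without 100 ppb replicate 1 (0.0333), without the 10 ppb pool (0.024) and in the trend fit (0.0414). With an estimated correlation their adjusted p was 0.888 with median scaling, 0.981 in the deposited scaling, 0.792 with pseudocount 64, 0.637 without a filter, 0.732 without the 10 ppb pool and 0.494 in the trend fit. The estimated correlation was not run with an array left out. No ribosomal, oxidative phosphorylation, cell cycle, proteasome, heat shock or Wnt gene passed on its own at any dose.

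Steroid synthesis genes had no passing member among 6 at any dose, over all genes or adjusted over the list alone. The list holds 24 genes, so most of it was not tested. cyp19a1a, the ovarian aromatase gene, differed by 0.24 ± 0.19, 0.18 ± 0.19 and 0.51 ± 0.19 at 10, 40 and 100 ppb (adjusted p = 0.586, 0.768 and 0.131), and by -0.07 at 10 ppb in the deposited scaling. The list's adjusted p was 0.710. Nor did lists pass for the aryl hydrocarbon receptor pathway (adjusted p = 0.215), adipose and endothelium (0.244), liver (0.263), Wnt signalling (0.405), lipid metabolism (0.457), estrogen receptors and vitellogenins (0.457), muscle (0.660), oxidative stress (0.660), granulosa and theca (0.660), heat shock and endoplasmic reticulum stress (0.775), exocrine pancreas and gut (0.799), retinoid metabolism (0.799), the proteasome (0.799) and growth factors (0.916). The deposited scaling passed the receptor pathway, vitellogenin and liver lists (5.81e-07, 2e-08 and 7.64e-20), each with adjusted p = 0.712 with an estimated correlation. Without the 10 ppb pool the liver list turned down and passed (0.0316), the vitellogenin list passed as lower (0.024) and the receptor pathway as higher (0.0493). The liver list passed as higher without the 40 ppb pool (0.000575) and pointed down in the trend fit without passing (0.109), where the receptor pathway (0.044) and lipid metabolism, as lower (0.0106), passed. Exocrine pancreas and gut genes passed as higher without the 100 ppb pool (0.0281). With an estimated correlation, a test added after the values were seen, 0 lists passed in either other scaling, without any exposed pool or in the trend fit. The smallest adjusted p there was 0.712 in the deposited scaling, 0.888 with median scaling, 0.732, 0.842 and 0.824 without the 10, 40 and 100 ppb pool, and 0.494 in the trend fit. As that test missed the planted list in the simulated data, these values cannot decide for or against the calls at the preset correlation. The red blood cell list had 2 tested genes and was not tested as a list. For retinoid metabolism the median was 0.03 and the mean -0.09, for heat shock the median was -0.01 and the mean 0.05, and for growth factors the test pointed down while the mean was 0.02 and the median 0.06.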

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

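Fits without the 10 ppb arrays, and without the liver list and discordant probe sets, were chosen after the data were seen, as were the other filters on the liver list, the bounds for dim probe sets and the estimated correlation under other settings; the other alternatives were planned. Of 1205 values of 99 named gene comparisons or trends under other settings, 1030 kept direction and side of the threshold, 169 kept direction and stopped passing, 3 started to pass and 3 reversed. With 1 array left out 617 of 780 stayed, 160 stopped passing, 1 started and 2 reversed. Of 93 named calls the deposited scaling ended 56. None of the reversed values passed at first: cyp19a1a at 10 ppb was -0.0662 in the deposited scaling, fabp10a, 10 ppb versus 0 ppb, was -0.0126 there (0.91 without 10 ppb replicate 2), -0.28 with scan day as a block and -0.26 without 10 ppb replicate 1, and rbp4 at 10 ppb was 0.45 without 10 ppb replicate 2 (-1.23 without replicate 1, -1.33 with scan day as a block).

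Counts are given in the order 10, 40 and 100 ppb against 0 ppb, 40 and 100 against 10 ppb, and 100 against 40 ppb, with 103, 32, 116, 91, 148 and 40 as reported. The deposited scaling gave 64, 4, 13, 61, 61 and 4; pseudocount 64 gave 61, 15, 44, 51, 74 and 17; a filter at the 60th percentile, which tests fewer probe sets, 37, 15, 49, 32, 62 and 20. No minimum difference gave 226, 57, 481, 137, 332 and 83, which follows from its construction, and a test against a minimum difference 49, 7, 31, 40, 61 and 8. With only the compared groups in the fit the counts were 42, 52, 132, 10, 61 and 63. Without a pseudocount 198 passed for 100 against 0 ppb, with scan day as a block 236 for 100 against 10 ppb, and without the 10 ppb arrays 61 for 100 against 40 ppb, 44 for 40 and 132 for 100 against 0 ppb. Without the liver list and discordant probe sets 47 passed for 10 against 0 ppb. Median scaling, no filter and no variance trend kept these 6 counts within 1.5 times. The cause was not tested except where stated.

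With 1 array left out, the lowest and highest counts were 19 (without control replicate 2) and 192 (without 10 ppb replicate 2) for 10 against 0 ppb, 7 (without 40 ppb replicate 1) and 42 (without either 10 ppb array) for 40 against 0 ppb, and 69 (without control replicate 2) and 130 (without 10 ppb replicate 2) for 100 against 0 ppb. They were 35 (without 40 ppb replicate 1) and 160 (without 10 ppb replicate 2) for 40 against 10 ppb, 68 (without 100 ppb replicate 2) and 222 (without 10 ppb replicate 1) for 100 against 10 ppb, and 10 (without 40 ppb replicate 2 or 100 ppb replicate 1) and 62 (without 10 ppb replicate 2) for 100 against 40 ppb. The lone array of a pool was then assumed to vary like the others. Exposed against control stayed at 0 (701 at an unadjusted p under 0.05 in limma's full fit), the trend ran from 1 (without control replicate 2, among others) to 7 (without 10 ppb replicate 1) and the gene lists from 5 to 7.

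Exposed against control called 24 probe sets in the deposited scaling and 66 with the 10 ppb pool as the odd one. The trend called 19 in the deposited scaling, 5 with median scaling, 1 with pseudocount 64, 9 with the filter at the 60th percentile, 0 without a variance trend, 123 without the 10 ppb pool, 4 without the 40 ppb pool, 0 without the 100 ppb pool, 0 with dose in ppb and 5 with log10 of dose plus 10. The number of lists called was 10 without the 10 ppb pool, against 6 as reported. With an estimated correlation, a test that missed the planted list in the simulated data, it was 0 as reported and in 8 other settings.

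Replicate numbers do not pair all arrays: deviations of equal numbers correlated across probe sets at 0.21, 0.14 and 0.30 among the 0, 40 and 100 ppb pools and at 0.01, 0.04 and 0.05 with the 10 ppb pool. With the replicate block the counts were 109, 29, 126, 103, 158 and 40. Signal over background limits dim genes: 63.6% to 79.5% of probe sets per array exceeded the 95th percentile of the tag controls.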

Other observations

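The tests that weigh explanations below were chosen after the results they bear on had been seen, and so was the comparison of days; the list medians were planned. The exocrine pancreas and gut list, with markers such as digestive protease genes, had no passing member among 6 tested genes at any dose in limma's test over all genes. Its median was nevertheless 0.58 at 10 ppb, 0.32 at 40 ppb and -0.63 at 100 ppb, at percentiles 99.96, 99.89 and 0.06 among 10000 random lists of like expression, and 2 members were higher at 10 ppb adjusted over the list alone. As for the liver list, the filter's mean includes the 10 ppb arrays, so a rise at 10 ppb can carry a gene past it. The oocyte list's median was 0.04, 0.09 and 0.18 at the 3 doses (percentiles 88.5, 97.6 and 99.9), and that of 5 granulosa and theca genes 0.01, 0.18 and 0.25 (percentiles 62.2, 92.6 and 94.0), with no passing member in either.

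Between the 2 days that the 0, 40 and 100 ppb pools shared, 3 probe sets differed in limma's test. On the later day the stress-response gene ddit4 was lower by -1.77 and syncripl by -1.57, and the translation factor gene eif4a1a was higher by 1.1.

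The 10 ppb pool carried more liver transcripts and less vitellogenin transcript than the control pool. vtg2, vtg4 and vtg3 also lay below control at 40 ppb (-1.05, -0.97 and -0.83) and 100 ppb (-1.07, -1.15 and -0.66). None of these passed in limma's test over all genes. For the liver genes, the day of the 10 ppb replicate 1 array is argued against as the whole source. Between the arrays of the shared day all 27 liver list genes, taken without a filter, had a median difference of 0.94 (range -2.21 to 3.36), above all 10000 random lists. Over both arrays per pool that median was 1.95, so replicate 1 or its day may account for part of the size. Whether the 2 arrays, labelled as technical replicates, hold the same RNA was not tested. An effect that holds or grows with dose is argued against too, since at 100 ppb the 12 genes passing at 10 ppb had a median of 0.0519 (range -0.55 to 1.32). For the lower vitellogenins, added liver that carries vitellogenin transcript would raise or leave them, since vtg2 is itself on the liver list. All 3 fell instead (-2.96 to -2.09). As ovary transcripts, they would be diluted by added liver at a fixed amount of RNA. Dilution alone is argued against: 27 oocyte genes had a median of 0.04 at 10 ppb, against -2.09 for the smallest of the 3 decreases. These 3 were picked because they passed as lower, so their size alone cannot decide. For the liver genes added liver stays open, as does a response at 10 ppb alone, which was not tested. Of 27, taken without a filter, 21 lay above both control arrays on both 10 ppb arrays. On the shared day, however, the list's fabp10a, rbp4 and vtg2 differed by -0.38, -1.35 and -2.21.

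The rise of cyp1a was weighed against the same liver signal. At 40 and 100 ppb a liver signal like that of the 10 ppb pool is argued against as its source. The higher of the liver list medians was 0.0422 while cyp1a differed by 3.13 and 4.04. A smaller share of liver was not tested. At 100 ppb 11 of 21 liver genes lay above 0 and 10 below, with serpina1l at 1.32 without passing. At 10 ppb the excess of cyp1a over control was 3.10 times as large on replicate 1 as on replicate 2, below 11 of the 12 passing liver genes (4.07 to 9.01) and above tfa alone (2.18). Among these 12, liver RNA as its whole source is thus left open by 1 gene. Genes off the list were not set against this ratio, such as hpxb, at 9.63 and 8.19 on the 10 ppb arrays. Induction in the ovary and liver RNA therefore cannot be told apart at 10 ppb. Exposure remains a candidate explanation for the higher doses, untested beyond 1 pool per dose.

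For the 24 probe sets lower at both 40 and 100 ppb, an additive difference between days cancels by design, since the 0, 40 and 100 ppb pools each had 1 array on either shared day. A count of calls left scaling open as a source. In the other 2 scalings the highest of the 24 was -0.73, with medians of -1.30 and -1.23 at 40 ppb. This later test could hardly fail and decides nothing. The 24 were selected for a decrease of at least 1, and these scalings shifted the median of all probe sets by 0.06 and 0.14 at 40 ppb. Calls did depend on the scaling, since 18 of 24 passed at both doses with median scaling and 2 in the deposited scaling. The median SE was 0.52 in the deposited scaling against 0.18 as reported. A loss of all cells other than oocytes is argued against by the granulosa and theca median at 100 ppb, 0.25 (range -0.34 to 0.76 over 5 genes) against -1.63 for these probe sets. Only 5 of 21 listed granulosa and theca genes were tested. At 100 ppb the medians were -0.50 for leukocyte, -1.28 for red blood cell (2 genes) and -0.30 for adipose and endothelium genes. The muscle median was 0.01. TCDD exposure may account for the decrease, but 2 of the 24 also passed the trend across pools, and with 1 pool per dose it cannot be told apart from a difference between groups of fish or, untested, a loss of part of the follicle or surface cells.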
